A study of Mus musculus with 6 samples.

How the data were processed

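RNA abundance was measured with Affymetrix Mouse Genome 430 arrays in early thymic progenitors, the most immature T-lineage precursors of the thymus, sorted by their surface markers as lineage-negative, CD44-positive, CD25-negative and kit-positive cells. The 6 arrays carry RNA of C57Bl/6 mice killed at 10 weeks of age, 3 arrays of Tcf1-/- and 3 of Tcf1-/+ animals. Tcf1 is a DNA-binding partner of beta-catenin that acts early in T-cell development. Per the labels' protocols, 1000 cells gave about 3 ng of total RNA on average, which was amplified with a whole-transcriptome kit, labelled with biotin and hybridized.

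Groups were taken from the sample titles, which name Tcf1-/- and Tcf1-/+. Another label field of the second group says wild type, so the control genotype is not settled by the labels, and it is called Tcf1-/+ throughout as in the titles. The titles call the arrays of a group biological replicates, and nothing says how many animals gave the cells of an array. Both groups number their replicates 1 to 3, and nothing in the labels says that a number marks a shared litter or day.

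The deposited values are log2 summaries per probe set. How the authors summarized and normalized them is not given in the sources used here. The scale was taken from the values, which lay between 2.15 and 14.8 with no missing entries. The array medians lay between 5.80 and 5.87. Values were used as deposited, with no further normalization. The 27 control probe sets for bacterial transcripts had a 95th percentile of 5.21, which was taken as the level of background. Where the mean of a genotype lies under it, the size of a difference is not well measured, and the gene is named as such. Arrays have no read depth, and the number of arrays limits the precision.

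The table held 45101 probe sets. The 64 control probe sets were left out, and 45037 were tested. The platform annotation gave 1 gene symbol to 34945 of these, several to 932 and none here to 9160. Gene identifiers of 34741 were found in the RefSeq gene table of the mouse assembly GRCm38.p6, used for names alone, and 0 symbols needed an update. No gene was named from a probe set with several symbols. Each of 18193 genes was represented by its probe set of highest mean over the 6 arrays, a choice blind to genotype. Tcf7, the gene that encodes Tcf1, had no probe set named in the annotation used here, so the planned check of the labels on the targeted gene was not made and Tcf7 was not analysed here. Columns of values that were not used numbered 0.

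Genotypes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, two-sided), over all 6 arrays and without covariates. P-values were adjusted by the Benjamini-Hochberg method over all tested probe sets, with a threshold of 0.05. Every difference is the Tcf1-/- mean minus the Tcf1-/+ mean on the log2 scale. Exact permutation of 3 arrays against 3 cannot give a p below 0.1, and so it was not used for single genes. The test was checked on simulated arrays with each probe set's mean over the 6 arrays. The spreads were limma's moderated ones, which are drawn towards a common value. Errors were drawn independently for each probe set, and 50 probe sets were changed at each of 4 sizes. Of all probe sets not changed, 2 were called, and 0 were called where nothing was changed.

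Gene lists, 19 in number, the rule for named genes and the alternatives were fixed before the data were examined, apart from those said to be added. Of the lists, 18 were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists. The lists cover T-lineage transcription factors, T-cell receptor assembly and signalling, the Notch and Wnt pathways, stem and progenitor genes, myeloid, B-lineage, NK and innate lymphoid, dendritic, erythroid, stromal, and double-positive and mature T-cell markers, cell cycle, survival, p53 target, cytokine and homing receptor, immediate early and interferon-stimulated genes. The sex-linked list was read per array without a test. Some list members had no probe set with 1 symbol and were not analysed here. A further 5 lists of natural killer, innate lymphoid, gamma delta and progenitor genes were written after the main comparison had been seen.

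The rule for the genes named in the text takes the 12 genes of largest rise and the 12 of largest fall past the threshold, with genotypes that do not overlap and a higher mean above the median of all probe sets. Where fewer passed, the lists were filled by the smallest unadjusted p with the other criteria kept. It adds up to 4 members of each list with the smallest adjusted p, and 17 regulators and lineage genes that are always given. Here 0 genes passed, so all 24 of the first kind were filled in by unadjusted p and none of them is past the threshold. Other genes that the text names were chosen after their values were seen, and are said to be so.

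The alternatives were the replicate number as a block, quantile normalization, a shift to a common median, a filter on probe sets below the 40th percentile of mean level, a floor at a log2 value of 5, trend and robust settings, array weights, leaving out each array, other thresholds, unmoderated tests per probe set, the mean of a gene's probe sets, leaving out probe sets with ambiguous suffixes, and 3 other set tests. The set tests were camera with an estimated correlation, fry, and the list median against 10000 random lists matched on mean level. After the sex-linked transcripts had been seen, the mean level of 3 Y-linked genes was added as a covariate, and the arrays with low Y-linked signal were compared alone. That leaves 1 array of Tcf1-/-, which is assumed to vary like the others.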

Results

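The comparison asked how early thymic progenitors that lack Tcf1 differ in gene expression from Tcf1-/+ progenitors of the same sort gate. There were 3 arrays of each genotype. Pairs of arrays correlated between 0.913 and 0.933 over all probe sets when Tcf1-/- replicate 2 was set aside. That array correlated with the other 5 between 0.870 and 0.893. It also stood apart in the control probe sets for the 3' and 5' ends of Tfrc. Their log2 difference was 0.055 on it and between -1.08 and -0.62 on the other 5. For Gapdh the difference was 2.78 on it, within the range of 1.74 to 2.885 on the other 5. The median SD of a probe set was 0.40 log2 units within Tcf1-/- and 0.34 within Tcf1-/+. No pair of arrays held identical values.

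Among the regulators fixed in advance, the largest difference was in Id2, an antagonist of E proteins and a regulator of innate lymphoid development. Its mean log2 level was 10.61 ± 0.64 (SD, n = 3) in Tcf1-/- and 7.42 ± 0.74 (SD, n = 3) in Tcf1-/+, a difference of 3.19 with a 95% confidence interval of 1.99 to 4.39. Il7r, the interleukin 7 receptor, was higher by 2.00, with an interval of 1.01 to 2.99. Lef1, the closest relative of Tcf1 named here, was lower in every Tcf1-/- array than in every Tcf1-/+ array, with a difference of -0.91 and an interval of -1.38 to -0.45. Flt3, a cytokine receptor of multipotent progenitors, differed by -1.53 (SE 0.42, from limma as all SEs of differences) and also did not overlap between genotypes. None of these differences passed limma's adjusted threshold over all probe sets, where Id2 had an adjusted p of 0.407.

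Of the T-cell receptor and recombination genes fixed in advance, Cd3e differed by -1.66 (SE 0.55), Cd3g by -1.92 (SE 0.90) and Rag1, a subunit of the V(D)J recombinase, by -1.88 (SE 0.66), and single arrays of both genotypes overlapped for each. The Tcf1-/- mean of Rag1 lay under the background level of 5.21. Of other members of these complexes, chosen after their values were seen, Cd3d differed by -1.06 (SE 0.41) without overlap between genotypes, Rag2 by -0.09 (SE 0.32) and Cd247 by -0.04 (SE 0.46). Kit, part of the sort gate, differed by -1.36 (SE 0.71), and by -0.61 on its other probe set. It was at 7.45 on Tcf1-/- replicate 2 and at 9.99 and 9.60 on replicates 1 and 3. The Tcf1-/+ arrays were at 10.80, 10.50 and 9.83, so the genotypes overlapped. Regulators of T-lineage commitment lay closer together. Gata3 differed by -0.39 (SE 0.40) and Bcl11b by 0.62 (SE 0.32). Il2ra, which encodes CD25 and was selected against by the gate, differed by 0.69 (SE 0.50) on its brighter probe set and by -1.29 on its other one. Of the Notch receptor and its targets, Notch1 differed by -0.38 (SE 0.36), Hes1 by -0.50 (SE 0.27), Dtx1 by -0.17 (SE 0.72) and Nrarp by 0.01 (SE 0.20). The myeloid regulators Spi1 and Cebpa differed by 0.01 (SE 0.29) and 0.25 (SE 0.77). The signs of Dtx1, Nrarp, Spi1 and Cebpa turned when single arrays were left out.

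**Figure D1:**
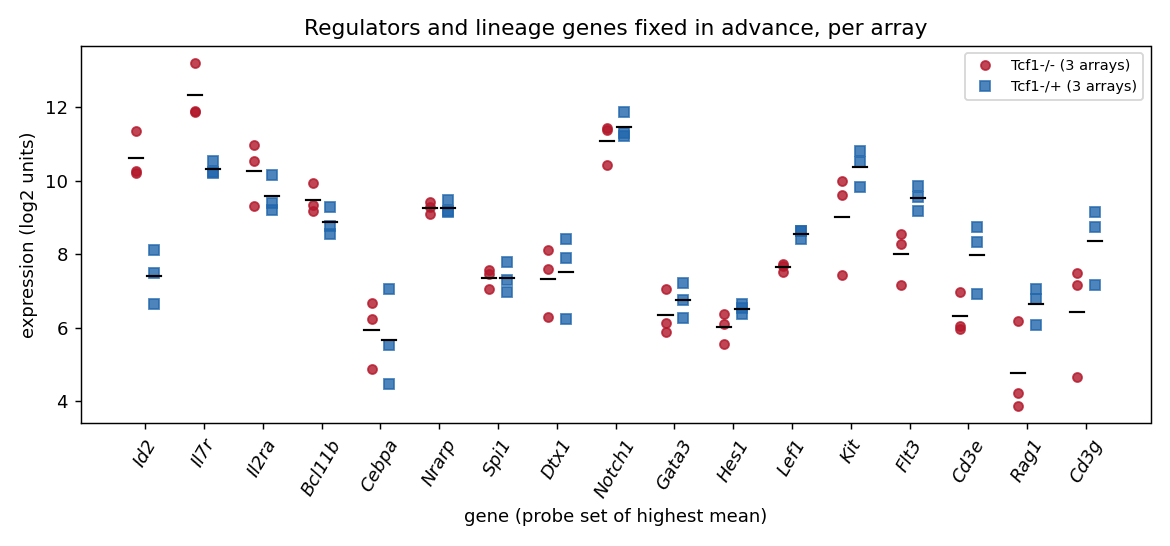
Expression in log2 units (vertical axis) of 17 genes fixed in advance (horizontal axis), with 1 point per array, circles for Tcf1-/- and squares for Tcf1-/+, and a bar at the mean of each 3 arrays. Id2 and Il7r lie higher and Lef1 and Flt3 lower on every Tcf1-/- array than on every Tcf1-/+ array, while Nrarp and Spi1 have nearly equal means.

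Over all 45037 probe sets, limma called 0 at an adjusted p of 0.05, and the lowest adjusted p was 0.315. At an unadjusted p under 0.05 there were 2917 probe sets, 1337 higher and 1580 lower in Tcf1-/-, where 2252 would be met by chance. The 3 arrays of a genotype allow an exact p no lower than 0.1. Unmoderated tests per probe set also called 0 after adjustment, with 1735 at an unadjusted p under 0.05 when variances could differ and 2565 when they were pooled. Of the 18193 genes, 1233 had an unadjusted p under 0.05, of which 789 differed at least 2-fold. The genotypes did not overlap for 12.2% of genes, where chance gives 10%. In simulated arrays with limma's moderated spreads and independent errors, 0% of probe sets changed by 1 log2 unit were called. The share called was 48% for a change of 2 log2 units, 68% for 3 and 88% for 4. The simulation held no differences that many probe sets of an array share. Its spreads also varied less between probe sets than the observed ones. The shares called may therefore not apply to the deposited arrays.

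The genes of smallest unadjusted p, none of them past the threshold, were of diverse kinds. The potassium channel gene Kcnk1 had a mean of 9.50 ± 0.83 (SD, n = 3) in Tcf1-/- and 4.42 ± 0.39 (SD, n = 3) in Tcf1-/+, a difference of 5.08 with an adjusted p of 0.323 from limma. The Tcf1-/+ means of Kcnk1, C5ar1, Dsp, Psd2, Phlda1, Ptprz1 and Tnfrsf25 and the Tcf1-/- means of Tifab, Plcxd2, A430093F15Rik and Lacc1 lay under the background level of 5.21, so that the sizes and the order of their differences are not well measured. The complement receptor gene C5ar1 differed by 4.85 (0.27 on its other probe set), the desmosomal gene Dsp by 4.78 and Psd2 by 4.54. Phlda1 differed by 3.74, Nrp1, a semaphorin co-receptor, by 3.27, Ptprz1 by 3.22, the thrombin receptor gene F2r by 2.79, Tnfrsf25 by 2.73, Stab2 by 2.51, Ccnt1 by 2.21 and Zscan12 by 1.71. Further probe sets of Kcnk1, F2r and Nrp1 had the same sign, while 1 other probe set of each of Ccnt1, Zscan12, Dsp and Rnf220 had the opposite sign. Among the genes lower in Tcf1-/-, Tifab differed by -3.19, Net1 by -2.93, Plcxd2 by -2.77, A430093F15Rik by -2.67, Tyw1 by -2.61 and Galnt11 by -2.39. They were followed by 4930515G01Rik at -2.18, Lacc1 at -2.15, Snx9 at -2.10, Rnf220 at -1.86, Defa3 at -1.33 and Ndufa6, a subunit of respiratory complex I, at -1.18. The lowest unadjusted p belonged to A430093F15Rik, with an adjusted p of 0.315 from limma.

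Of the NK and innate lymphoid markers, 16 of 23 measured members had a higher and 7 a lower mean in Tcf1-/-, and the list passed camera with an adjusted p of 0.00644. It had an adjusted p = 0.675 with an estimated correlation, and over all alternatives its adjusted p lay between 0.000305 and 0.675. Adjusted over the list alone, 5 members passed, all higher in Tcf1-/-, and 0 passed over all probe sets. Gzmb, a cytotoxic granule protease, differed by 4.06 (SE 0.69), Icos, a costimulatory receptor, by 3.22 (SE 0.56), Il18r1, an interleukin 18 receptor chain, by 2.43 (SE 0.56), and Id2 as given above. The fifth was the chemokine receptor gene Cxcr6, with a difference of 4.50 from a Tcf1-/+ mean under background, chosen after its values were seen. Of the 7 members with lower means, Klrd1 differed by -1.49 (SE 0.60) without overlap between genotypes, and was also chosen after its values were seen. The list mean was 1.03 and its median 0.19. Both means lay under background for 4 of the 23 members, and of the 19 others 13 had higher means, with a median of 1.26. The 3 Tcf1-/- arrays lay at 0.62, 1.37 and 1.11 on the list mean of centred values, against -0.15, 0.35 and -0.20 for Tcf1-/+. On the arrays with low Y-linked signal alone, 1 of Tcf1-/- and 2 of Tcf1-/+, the list had an adjusted p of 0.107 and a median of -0.01, and the call also ended with fry at 0.394 and against random lists at 0.227.

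Stem and progenitor genes had lower means in Tcf1-/- for 20 of 25 members and higher for 5. The list passed camera with an adjusted p of 0.000382 and had an adjusted p = 0.675 with an estimated correlation. Over all alternatives the adjusted p lay between 2.21e-05 and 0.675. The median difference was -0.51, with an adjusted p of 9e-04 against random lists. Cd34, a surface marker of progenitors, differed by -1.24 (SE 0.36), Hoxa9 by -0.99 (SE 0.39), Bcl11a by -0.52 (SE 0.21) and Flt3 as given above, and 0 members passed adjusted over the list alone. The list mean of centred values was -0.97 on Tcf1-/- replicate 2, -0.18 on replicate 1 and -0.32 on replicate 3, against 0.02, -0.29 and 0.27 on the Tcf1-/+ arrays, so the genotypes overlapped. Without Tcf1-/- replicate 2 the adjusted p was 0.0546, and on the arrays with low Y-linked signal it was 0.294, and with fry 0.394.

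Cell cycle genes had lower means in Tcf1-/- for 22 of 28 members, with a camera adjusted p of 0.00331 and an adjusted p = 0.675 with an estimated correlation. Plk1, a mitotic kinase, differed by -1.15 (SE 0.18) and was the 1 member that passed adjusted over the list alone. Top2a, a topoisomerase, differed by -1.18 (SE 0.33) on its brightest probe set, though 1 of its other probe sets had the opposite sign. Kif11 differed by -0.99 (SE 0.38), with the opposite sign on 1 other probe set, and the proliferation marker Mki67 by -0.42 (SE 0.20). Over all alternatives the adjusted p lay between 5.08e-06 and 0.818. The list mean was -0.93 on Tcf1-/- replicate 2, 0.12 on replicate 1 and -0.35 on replicate 3, against -0.06, -0.20 and 0.26 on the Tcf1-/+ arrays, so the genotypes overlapped. Without replicate 2 the adjusted p was 0.212 and the median of the members 0.02. Without Tcf1-/+ replicate 3 the adjusted p was 0.0528, with the Y-linked level as a covariate 0.0521, and on the arrays with low Y-linked signal 0.818. It was 0.568 with fry and 0.307 against random lists.

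In the list of T-cell receptor assembly and signalling genes, 17 of 26 members had lower and 9 higher means, with a camera adjusted p of 0.0219 and an adjusted p = 0.675 with an estimated correlation. Adjusted over the list alone, 4 members passed, 2 with lower and 2 with higher means. Cd28, a costimulatory receptor, differed by -2.97 (SE 0.69), with a Tcf1-/- mean under background, and Dntt, the template-free polymerase of junctional diversity, by -1.36 (SE 0.33). Thy1, a surface glycoprotein of T-lineage and innate lymphoid cells, differed by 2.48 (SE 0.52) and Il7r as given above. Over all alternatives the adjusted p lay between 0.0035 and 0.675. The list mean of centred values was -0.68, -0.31 and -0.14 on the Tcf1-/- arrays. It was -0.28, 0.40 and -0.12 on the Tcf1-/+ arrays, so the genotypes overlapped. The call ended without Tcf1-/- replicate 1 at 0.354, without Tcf1-/- replicate 2 at 0.0574 and without Tcf1-/+ replicate 2 at 0.257, and on the arrays with low Y-linked signal at 0.107. It also ended with the replicate block at 0.0786, the filter on mean level at 0.153, the floor at 0.0637, fry at 0.568 and random lists at 0.221.

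Interferon-stimulated genes had higher means in Tcf1-/- for 13 of 18 members, with a camera adjusted p of 0.00644 and an adjusted p = 0.675 with an estimated correlation. Rtp4 differed by 1.52 (SE 0.24) and was the 1 member that passed adjusted over the list alone. Dhx58, a cytosolic RNA sensor, differed by 1.37 (SE 0.35), Ifit3 by 1.48 (SE 0.62) and the transcription factor gene Irf7 by 0.81 (SE 0.32). Over all alternatives the adjusted p lay between 3.43e-06 and 0.675. The list mean was 0.95 and 0.75 on Tcf1-/- replicates 2 and 3 and -0.20 on replicate 1, against 0.05, -0.03 and -0.02 on the Tcf1-/+ arrays, so the genotypes overlapped. On the arrays with low Y-linked signal the direction turned, with an adjusted p of 0.531, and the call also ended without Tcf1-/- replicate 2 at 0.0837 and without Tcf1-/- replicate 3 at 0.189. With fry the adjusted p was 0.394, and against random lists it was 0.03.

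**Figure D2:**
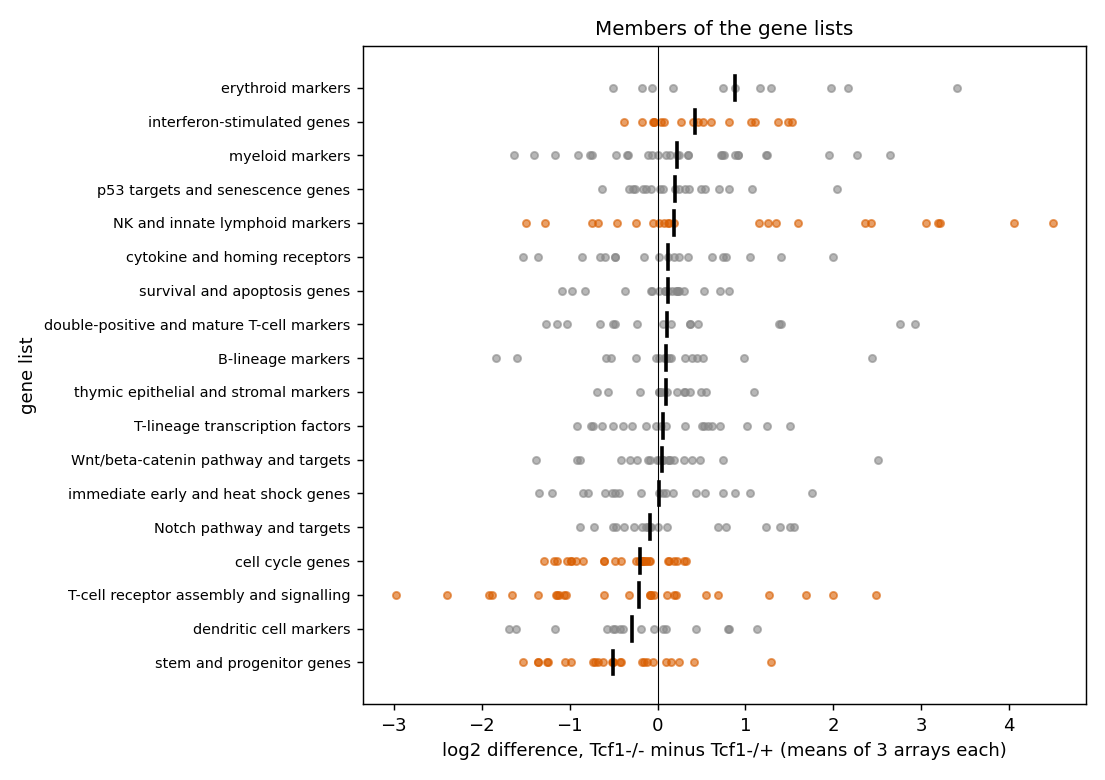
Log2 difference between the genotype means (horizontal axis, Tcf1-/- minus Tcf1-/+) for each measured member of 18 gene lists (vertical axis), with 1 point per gene and a black bar at the list's median. Orange marks the 5 lists past camera with the preset correlation, of which the stem and progenitor list has the lowest median at -0.51.

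The other 13 lists did not pass camera. Their counts include members with both means under background, which numbered 6 of the stromal, 5 of the B-lineage, 5 of the p53, 4 of the Wnt, 3 of the myeloid and 2 of the erythroid list, and at most 2 of any other of the 13. Of the T-lineage transcription factors, 11 had higher and 9 lower means, and Satb1 differed by -0.73 (SE 0.23), Sox4 by -0.76 (SE 0.27) and Tcf3, which encodes E proteins, by 1.51 (SE 0.63). Of the Notch pathway and targets, 8 had higher and 11 lower means. Igf1r differed by 1.55 (SE 0.36), Hey1 by 1.39 (SE 0.42) and Myc by -0.88 (SE 0.41). Of the Wnt genes, 13 had higher and 9 lower means, with Rnf43, a feedback inhibitor of the pathway, at 2.50 (SE 0.58) and Tle4, a co-repressor, at -1.39 (SE 0.77). Other probe sets had the opposite sign for Tle4, at 1.06, and for Igf1r, at -0.29, and the Tcf1-/+ mean of Rnf43 lay under background. The median and the camera direction differed in sign for these 3 lists, whose camera adjusted p were all 0.896.

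Markers of other cell types were mixed. Of the myeloid markers, 18 of 29 had higher means (camera adjusted p = 0.743), and Fcer1g, a signalling chain of Fc and NK receptors, differed by 2.27 (SE 0.31) and passed adjusted over the list alone. S100a8 differed by 2.64 (SE 1.14), Ngp by 1.95 (SE 0.77) and Irf8 by -1.17 (SE 0.55), with 0.26 on a further probe set. The Tcf1-/+ mean of Ngp lay under background, as did the Tcf1-/- mean of the B-lineage gene Pou2af1. Of the B-lineage markers 12 of 18 had higher means (camera adjusted p = 0.787), with the kinase gene Blk at 2.44 (SE 0.63) and Pou2af1 at -1.84 (SE 0.46). Of the dendritic markers 10 of 16 had lower means (camera adjusted p = 0.413), with the class II genes Cd74 at -1.61 (SE 0.46) and H2-Eb1 at -1.69 (SE 0.66). Of the double-positive and mature T-cell markers 9 of 16 had higher means (camera adjusted p = 0.787). Among them Cd4, a co-receptor, differed by 2.93 (SE 0.61) and passed adjusted over the list alone, while Cd69 differed by 1.38 (SE 0.45) and Gimap6 by -1.03 (SE 0.35). Of the erythroid markers 8 of 11 had higher means, with Car1 at 3.41 (SE 1.52) and Klf1 at 1.97 (SE 1.23), and a camera adjusted p of 0.101. The erythroid list mean was 1.35, -0.05 and 1.72 on the Tcf1-/- arrays and -0.80, -0.62 and 1.43 on the Tcf1-/+ arrays, and its adjusted p over all alternatives lay between 0.000545 and 0.822. Without Tcf1-/+ replicate 3 the adjusted p was 0.000545 for the erythroid list and 0.00886 for the myeloid list, whose range was 0.00886 to 0.987, and without Tcf1-/- replicate 2 it was 0.0114 for the erythroid list. The erythroid list also passed with the replicate block at 0.0274, with array weights at 0.0206, with the Y-linked level as a covariate at 0.0304 and against random lists at 9e-04. With camera at an estimated correlation the adjusted p was 0.822 for the erythroid and 0.903 for the myeloid list. With fry it was 0.728 for each of these lists.

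Of the survival and apoptosis genes, 13 of 19 had higher means (camera adjusted p = 0.896), with the anti-apoptotic gene Bcl2 at 0.81 (SE 0.25), Apaf1, an apoptosome component, at -0.97 (SE 0.26) and Birc2 at -1.09 (SE 0.37). All 5 probe sets of Bcl2 had higher Tcf1-/- means. Of the p53 targets and senescence genes 12 of 19 had higher means (camera adjusted p = 0.413), with Gadd45a at 2.04 (SE 0.99) from a Tcf1-/+ mean under background. Both means of Cdkn2a, a senescence gene, lay under background, so no difference is given. Of the cytokine and homing receptors 11 of 19 had higher means (camera adjusted p = 0.896), with Il17rb, an interleukin 25 receptor chain, at 1.05 (SE 0.31), and Il7r was the 1 member that passed adjusted over the list alone. Egr1 differed by 1.75 (SE 0.61) and Dusp1 by 1.06 (SE 0.36) among 19 immediate early and heat shock genes, of which 10 had higher means (camera adjusted p = 0.998). Their median was 0.02 and their mean -0.03. Of 16 thymic epithelial and stromal markers 13 had higher means (camera adjusted p = 0.413), with Dll4 at 0.50 (SE 0.24) from a Tcf1-/+ mean under background.

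Sex-linked transcripts differed between the arrays of each genotype. Xist, expressed from the inactive X chromosome of females, was at a log2 level of 5.12 on Tcf1-/+ replicate 2 and between 12.87 and 13.45 on the other 5 arrays. The Y-linked gene Kdm5d was at 10.93 on Tcf1-/+ replicate 2, at 4.47 and 4.29 on Tcf1-/+ replicates 1 and 3, at 5.40 on Tcf1-/- replicate 1, and at 9.82 and 10.34 on Tcf1-/- replicates 2 and 3. Tcf1-/- replicates 2 and 3 therefore carried Xist and Y-linked signal together. With the Y-linked level as a covariate, limma again called 0 probe sets, with 2850 at an unadjusted p under 0.05, and on the arrays with low Y-linked signal it called 0, with 3494 at an unadjusted p under 0.05.

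**Figure D3:**
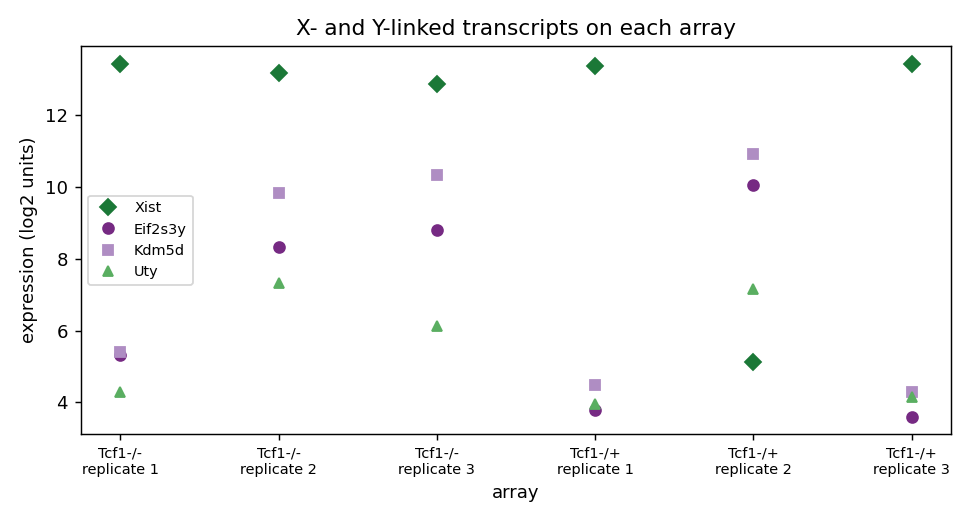
Expression in log2 units (vertical axis) of Xist and the Y-linked genes Eif2s3y, Kdm5d and Uty on each of the 6 arrays (horizontal axis), with 1 point per gene and array. Xist is at 5.12 on Tcf1-/+ replicate 2 alone, and the Y-linked genes are high on that array and on Tcf1-/- replicates 2 and 3.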

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

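The covariate for the Y-linked level and the comparison of arrays with low Y-linked signal were chosen after seeing the data. Under every alternative that used an adjusted p, limma and the unmoderated tests called 0 probe sets and 0 genes, with between 1735 and 3494 probe sets at an unadjusted p under 0.05; at an unadjusted p under 0.05 with a 2-fold change the counts were 1875 and 789. Same-numbered arrays deviated from their group means with correlations of 0.0298, 0.0445 and 0.0117. Unlike-numbered arrays had correlations between -0.0899 and 0.0612. These values gave no sign that the numbers pair the arrays, but they cannot exclude a shared litter or day. The replicate block called 0 probe sets (3074 at an unadjusted p under 0.05), and gave an adjusted p of 0.0786 for the T-cell receptor list and 0.0274 for the erythroid list. Of 107 named genes, 100 kept their sign under every alternative that gave a value. This count partly follows from how the genes were chosen. The genes of smallest unadjusted p had to have genotypes that do not overlap, and leaving out an array cannot turn the sign of such a gene. The cause of the changes below was not tested.

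The T-cell receptor list had an adjusted p of 0.153 with the filter on mean level, 0.0637 with the floor, 0.107 on arrays with low Y-linked signal, 0.675 with an estimated correlation, 0.568 with fry, 0.221 against random lists, and between 0.0035 and 0.354 leaving out arrays. The stem and progenitor list had 0.294 on low-Y arrays, 0.675 with an estimated correlation, 0.394 with fry, and between 2.21e-05 and 0.0546 leaving out arrays. The NK and innate lymphoid list, which kept its call when any 1 array was left out, had 0.107 on low-Y arrays, 0.675 with an estimated correlation, 0.394 with fry and 0.227 against random lists. Cell cycle genes had 0.0521 with the Y covariate, 0.818 on low-Y arrays, 0.675 with an estimated correlation, 0.568 with fry, 0.307 against random lists, and between 5.08e-06 and 0.212 leaving out arrays. Interferon-stimulated genes had 0.531 and downward on low-Y arrays, 0.675 with an estimated correlation, 0.394 with fry, and between 3.43e-06 and 0.189 leaving out arrays. Erythroid markers had 0.0206 with array weights, 0.0304 with the Y covariate and 9e-04 against random lists. They had 0.822 with an estimated correlation, 0.728 with fry, and between 0.000545 and 0.742 leaving out arrays. Myeloid markers had values between 0.00886 and 0.987 leaving out arrays.

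Signs turned for 7 named genes under the alternatives given here. Leaving out arrays gave -0.36 to 0.93 for Cebpa, -0.81 to 0.35 for Dtx1, -0.069 to 0.11 for Nrarp, -0.18 to 0.22 for Spi1 and -0.25 to 3.91 for Xist. With the Y covariate Dtx1 was 0.00081, Spi1 -0.078 and Uty -0.092. On low-Y arrays Il2ra was -0.37 and Nrarp -0.21, and array weights gave Nrarp -0.0036. With the mean of a gene's probe sets Il2ra was -0.30 and Uty -0.0075, and without ambiguous suffixes Uty was -0.092. The planned pseudocounts did not apply to log2 values, Tcf7 was not analysed here, and the floor gave no value for Fosb, which lay under it.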

Other observations

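The tests on members outside the fixed lists, the spread and the level above background required to argue against a cell type, the covariate for the Y-linked level and the test of mixed sexes were chosen only after the result was seen. Genes of group 3 innate lymphoid and lymphoid tissue inducer cells, written as a list after the main comparison, had higher means in Tcf1-/- for 14 of 14 measured members, of which 12 had a mean above background. Ccr6, a chemokine receptor of these cells, had a difference of 3.56 (SE 0.59), with a mean of 9.97 in Tcf1-/- and 6.40 in Tcf1-/+. Cxcr5 differed by 3.30 (SE 0.64), lymphotoxin alpha (Lta) by 2.01 (SE 0.55) and the aryl hydrocarbon receptor gene Ahr by 1.47 (SE 0.41), while Ltb differed by 0.24 (SE 0.42). The Tcf1-/+ means of Cxcr5 and Lta lay under the background level of 5.21, so the sizes of their differences are not well measured, and both means of Il17a and Tnfsf4 lay under it. These genes were chosen after their values were seen, and none passed limma's adjusted threshold.

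Among 19 measured genes of erythroid and myeloid progenitors on another such list, 15 had higher means in Tcf1-/-, with a median of 0.72, and 7 of the 19 stand on the fixed lists too. Of the 12 others 10 had higher means, with a median of 0.43. Mcpt8, a basophil protease, differed by 3.14 (SE 0.60) and the mast cell protease gene Cpa3 by 1.09 (SE 0.37). Blvrb was at 9.80 on Tcf1-/+ replicate 3 and at 5.56 and 5.20 on the other Tcf1-/+ arrays, and Elane was at 9.83, 5.12 and 5.39 on the same arrays. These genes, too, were chosen after their values were seen.

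The innate lymphoid pattern, with the 5 list members that passed adjusted over the list alone, had a median difference of 3.22, with Cxcr6 under background in Tcf1-/+. For these 5 members the median was 3.044 (1.98 to 4.48) with the Y-linked level as a covariate. Without Tcf1-/- replicate 2 it was 2.82 (2.14 to 4.51). These members were picked for their difference on these same arrays, and the genotypes did not overlap for any of them. Leaving out 1 array could therefore hardly remove their difference. These values cannot decide whether the sex of the animals or the array that stands apart caused the pattern. The list as a whole had a median of 0.19. On the arrays with low Y-linked signal, with 1 of Tcf1-/-, the list median was -0.01. The 5 members had a median of 3.19 (2.06 to 4.14) on these arrays. Natural killer cells stay open. Their list had a median of 0.0715 over 17 members and 0.0773 over the 8 outside the fixed lists, under the bound first set. Of the 17, 10 had higher means. Among genes chosen after their values were seen, Gzma differed by 3.05 (SE 1.14), Klrd1 by -1.49 (SE 0.60) and Nkg7 by -0.67 (SE 0.52). Both means lay under background for 5 of the 17, namely Klra1, Klra8, Klre1, Ncr1 and Tbx21. For Eomes the Tcf1-/- mean of 4.80 lay under it too, against 5.55 in Tcf1-/+. These genes gave no sign of such cells, though levels under background are not well measured. High Tcf1-/+ levels, as of Prf1 at 9.50 and Nkg7 at 9.74, would hide a small share of such cells in the genes concerned. Group 3 innate lymphoid cells may have passed the gate, which selected against lineage markers and CD25 and for CD44 and kit. Their list had a median of 1.113, but 3 of its 14 members stand on the fixed lists, Cxcr6 in the pattern itself. The 11 others had 0.976, or 1.07 with an SD of 1.14 over the 9 above background. Such cells and a change within the progenitors therefore cannot be told apart. The genotype stays an open explanation that was not tested apart from cell content.

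Of 15 group 2 innate lymphoid genes 12 had higher means, with a median of 0.3197, and the 12 outside the fixed lists had 0.4561 with an SD of 0.51. Both means lay under background for 5 of the 15, all counted as higher, and of the 10 others 7 had higher means, with a median of 0.23. Of 7 innate-like gamma delta genes 5 had higher means, with a median of 0.0516, and the 6 outside the fixed lists had 0.3142 with an SD of 0.97. Both means lay under background for 1 of the 7. The bounds first set were a median above 1 for such cells and below 0.5 against them, by which the group 3 list counted for such cells and the natural killer, group 2 and gamma delta lists against them. The later requirements, on the members outside the fixed lists, their spread and their level above background, leave all of these open. To count against such cells, the median plus the SD had to lie below 0.5, also over the members above background alone. The natural killer list missed this only above background. Its 8 members outside the fixed lists had an SD of 0.35, and the 5 of them above background a median of 0.077 with an SD of 0.45.

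Tcf1-/- replicates 2 and 3 carried Xist and Y-linked signal together. A mixture of RNA from male and female animals on 1 array is a candidate explanation, in which the Y-linked share, relative to Tcf1-/+ replicate 2, and the Xist share, relative to the Tcf1-/+ arrays without Y-linked signal, would sum to between 0.7 and 1.3. The sums were 1.309 on replicate 2 and 1.11 on replicate 3, so the first lay just outside that range and the question stays open. No biological explanation was tested.

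The 6 arrays can be split into 3 and 3 in 10 ways with the real one, too few for a share under 0.05. For probe sets and for genes past the threshold the real split gave 0 and the highest other 1, and all 10 gave as many. For probe sets at an unadjusted p under 0.05 with a 2-fold change it gave 1875 and the highest other 1584, so 1 split was as large. For gene lists past camera it gave 5 and the highest other 7, and 3 splits were as large. With an estimated correlation the real split gave 0 lists and the highest other 2. The split with 1584 probe sets was also the one with 7 lists, and it sets the 3 arrays with low Y-linked signal against the 3 with high signal. With the Y-linked level as a covariate the cell cycle list had an adjusted p of 0.0521, the erythroid list 0.0304, and the other 4 lists past camera stayed past it at the preset correlation. Without the covariate, the adjusted p = 0.822 with an estimated correlation for the erythroid list and 0.675 for the 5 lists.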
